A study of Mus musculus with 167 samples.

How the data were processed

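The series holds 167 mouse samples, and 104 libraries were used here: 56 libraries of Igh V(D)J joins, 44 RNA libraries and 4 CTCF peak sets. The mice were of the C57BL/6 strain. V(D)J joins were read from sorted bone marrow pro-B cells by extending biotinylated primers in the JH segments, which captures DNA joined to JH, and the adapters carried unique molecular identifiers. RNA was sequenced from pro-B, pre-B and immature B cells, from pro-B cells expanded in culture, and from progenitors lacking Pax5. CTCF, a DNA-binding protein at which cohesin loops often end, was mapped by chromatin immunoprecipitation in cultured pro-B cells. Chromosome conformation, open chromatin, histone and other protein maps were not analysed here, and 14 chromosome conformation samples could not be assigned to a group. The series also holds CTCF samples of the CBE and CBE-inv alleles, which were not analysed either.

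The V(D)J values are percent per V gene as deposited, 1 file per library. Their sum per library is well under 100, so the deposited percent refers to a total that also holds reads not listed, and that total is not given in the sources used here. Depth is therefore unknown, no counts were inferred, and no counting interval or detection limit is given. The submitters' processing notes name build mm10 and R 3.3.3 for these files. The aligner and the V gene caller are not given in the sources used here, nor is the use made of the molecular identifiers, so a join amplified more than once could still count more than once. Reads shared between similar V genes could also be lost or assigned to the wrong member.

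The RNA values are TPM (transcript abundance scaled to a fixed library total) computed by the authors over their own gene rows. In 11 of the 44 RNA libraries the deposited column has a library number as its header and is recorded as signal, but its values sum to the same total as in the others and were treated as TPM. The peaks, recorded as other, were deposited by the authors as start and end positions with a score of 0 in every row. The series text places the control peaks on mm9 and the 890-inv peaks on a build modified for that allele. The submitters' processing notes for all assays other than V(D)J joins name builds mm9 and mm10, MACS, Bowtie 1.0, Bowtie2 2.1.0 and 2.2.9, featureCounts 1.5.0, DESeq2 2.1.14.1, MACS2 2.0, bedtools, SAMtools 1.4, cutadapt 1.16, Trim Galore 0.4.2, Juicer 1.8.9, R 3.3.3 and R 3.4.1, without roles. TPM values are relative within a library, so a large change in a few abundant transcripts shifts the rest. Read depth per RNA library is unknown from these files, which limits what can be said of low values.

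Groups were taken from the genotype and cell type labels. Each RNA comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a trended prior, for genes at 1 TPM or more in at least as many libraries as the smaller group holds. Folds given for RNA are ratios on that scale, so for genes near 0 TPM they depend on the pseudocount. The Eed comparison included the library series as a term, and its 4 RNA controls were 1 library without Cre and 3 with 1 floxed allele. In the V(D)J run the Eed controls were a wild type and an Eed heterozygote, both without Cre, and all 4 mutants carried Cre at Rag1. Of the 3 libraries lacking Pax5 there, replicate 1 is labelled with 1 Rag2 allele and the others with both. V8-8-inv replicate 2 carries further genotype text in its label, which also names the CBE alleles, and was kept in its group. The pro-B and pre-B libraries of the Wapl mutant shared 1 fit, from which the difference between the mutant effects in the 2 stages was tested. For V(D)J joins, each V gene was expressed as its share of the listed V total in its library, and log2(share + 0.02) was fitted with limma for genes at a share of 0.05 or more. Shares sum to 100, so a fall of one family raises the rest, and the deposited percent is given beside the main results. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, and all tests were two-sided. The share of the distal families was compared by exact permutation tests, adjusted over 13 comparisons.

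V genes were grouped by family as distal (Ighv1 and Ighv8), proximal (Ighv2 and Ighv5, next to the D and J segments) and middle (the other families), and positions are those of the GRCm38 annotation. The 24 gene lists covered cohesin, Polycomb repressive complex 2 and its targets, genes activated or repressed by Pax5, pre-B cell receptor signalling, V(D)J recombination, B-lineage factors, light chains, markers of mature B, plasma, T and innate lymphoid, myeloid, plasmacytoid dendritic and erythroid cells, cell cycle, p53 targets, interferon response, immediate early and heat shock genes, glycolysis, sex-linked genes and the V gene families. Lists were tested with fry, which asks whether the members move on balance one way and does not compare them with other genes, and again with camera using an estimated correlation. The p-values of fry depend on the order of the groups in the design matrix. The order of the first run was kept, and the other order was tried after its effect was seen. Lists, groups, tests and alternatives were fixed before the data were examined, except those named as chosen later.

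Named RNA genes were the targeted genes, the 8 largest rises and 8 largest falls among called genes with no overlap between groups and at least 5 TPM in the higher group, up to 4 called members of each list, and the 5 largest rises and falls of called V genes. Predicted genes with Gm or Rik symbols were left out, and 1 gene that the rule takes is not reported here. Named V genes in V(D)J joins were the 5 largest rises and falls in percentage points, with Ighv5-2, Ighv2-2, Ighv14-2, Ighv1-26 and Ighv8-8 always included. CTCF peaks were compared by overlap with bedtools 2.31.1, and other steps used Python 3.11.15.

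The fits were tested on simulated data. With the pro-B design, 75% of simulated 2-fold and 94% of 4-fold changes were recovered, the highest of the RNA designs tried, and 6.63% of calls were false. The V8-8 RNA design recovered 49% and 88%, and the 890-inv RNA design 58% and 80%. The Eed V(D)J design recovered 10% of 4-fold changes. Alternatives were other pseudocounts, no filter, quantile normalization of TPM, V gene values as deposited, fewer groups in the fit and leaving out each library in turn. P-values measure only the spread between samples, which may share mice, days or cell preparations that the labels do not give.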

Results

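The libraries address how the level of Wapl, the factor that releases cohesin from chromatin, and the arrangement of the Igh locus relate to the choice of V genes in developing B cells. The alleles carry deletions labelled P1, P2 or both at Wapl (dP1, dP2 and dP1,2), or changes of the Igh locus labelled 890-inv, V8-8, V8-8-inv, CBE and CBE-inv. Cells lacking Pax5, the transcription factor that commits progenitors to the B lineage, or labelled as lacking Eed, a core subunit of Polycomb repressive complex 2, were compared in the same assays. Below, the words without Eed refer to that label. Values are mean ± SD.

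Wapl RNA was higher in every dP1,2 comparison and in progenitors lacking Pax5. It rose from 10.7 ± 0.446 TPM (n = 2) in wild-type pro-B cells to 31.3 ± 0.547 TPM (n = 2) in dP1,2 homozygous pro-B cells, 2.76-fold (limma, adjusted p = 0.000632). Pre-B cells rose from 11.1 ± 2.54 to 46.8 ± 1.49 TPM, 3.99-fold (adjusted p = 0.000203). Cultured pro-B cells rose from 9.82 ± 3.42 (n = 2) to 38.2 ± 12.7 TPM (n = 3, adjusted p = 0.00403). Progenitors lacking Pax5 had 33.8 ± 2.44 TPM (n = 2) against 8.98 ± 4.02 TPM (n = 3) in wild-type pro-B cells (adjusted p = 0.00266). In cells labelled as lacking Eed, Wapl was at 11.2 ± 1.88 TPM (n = 5) against 4.57 ± 4.25 TPM in controls (n = 4), and the difference did not pass the test (adjusted p = 0.0696).

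**Figure D1:**
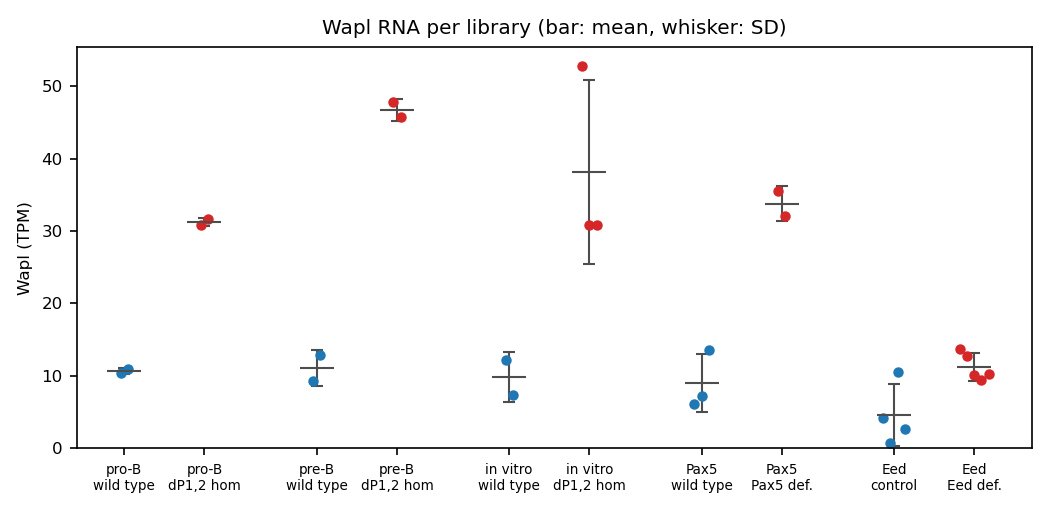
Wapl RNA in TPM for each library (points), with the mean (bar) and SD (whisker) of each group; blue marks controls and red the mutant groups. The dP1,2 groups average 31.3, 46.8 and 38.2 TPM, and their controls 10.7, 11.1 and 9.82 TPM.

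In dP1,2 homozygous pro-B cells, V(D)J joins shifted to the V genes nearest the D segments. Ighv5-2, on chromosome 12 from 113578504 to 113578990, rose from 6.01% ± 0.546 to 34.3% ± 0.327 of the listed V total (n = 2 each, limma, adjusted p = 2.21e-06), and its neighbour Ighv2-2 rose from 3.38% ± 0.222 to 20.9% ± 1.58. Ighv1-26 fell from 2.62% to 0.271% and Ighv8-8 from 1.45% to 0.149%. Of the genes tested, 68 of 69 distal and 32 of 33 middle genes fell, while among 17 proximal genes 10 rose and 5 fell. As deposited, 3 of these proximal genes were called higher and 11 lower. The distal families together took 49.0% ± 1.11 of joins in wild-type, 11.3% ± 0.726 in heterozygous and 5.40% ± 0.239 in homozygous cells. For these groups of 2 the exact permutation test gave p = 0.3333 in both comparisons, the smallest this design allows. In heterozygous cells 105 of 119 genes were called, against 115 in homozygous cells, and Ighv5-2 took 28.0% ± 0.507. The listed V total was lower as well, going from 48.7% ± 0.247 to 17.0% ± 0.129 in heterozygous and 10.1% ± 0.354 in homozygous cells. As deposited, the proximal families summed to 10.6% ± 0.480 in wild-type, 8.88% ± 0.364 in homozygous and 13.1% ± 0.176 in heterozygous cells, and Ighv5-2 itself was at 2.93% and 3.47% in wild-type and homozygous cells.

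In dP1 pro-B cells the distal share went from 45.8% ± 2.40 to 13.6% ± 0.925 (n = 3 each), with 65 of 68 distal and 31 of 31 middle genes falling and Ighv5-2 rising from 6.60% ± 0.935 to 26.9% ± 1.16 (limma, adjusted p = 2.88e-18). That p-value leans on spread pooled across genes (50.1 degrees of freedom for 6 libraries). The listed V total there was 46.9% ± 0.789 in controls and 17.9% ± 0.811 in dP1 cells, and the proximal families as deposited summed to 11.4% ± 1.32 and 13.1% ± 0.286. In dP2 pro-B cells the distal share went from 48.9% ± 0.846 to 42.7% ± 0.717 (n = 3 each). There 21 of 69 distal genes fell, 15 of 18 proximal genes rose, and Ighv5-2 rose from 5.70% ± 0.0678 to 6.84% ± 0.260 (adjusted p = 0.0013). The exact permutation p was 0.1 for the distal share in both runs, the smallest that 3 against 3 allows. As deposited, no distal gene was called lower in dP2 cells and 2 were called higher. The distal sum was 24.1% ± 1.18 in control and 24.7% ± 0.585 in mutant, and the proximal sum 10.4% ± 1.08 and 15.9% ± 0.789. Of 32 middle genes, 12 were called higher and 0 lower as deposited, and the middle sum was 14.83% ± 1.03 and 17.36% ± 0.268. The listed V total was higher too, at 46.2 to 52.7% in control and 57.2 to 59.4% in dP2 libraries. The difference between the dP1 and dP2 effects, which come from separate runs, was not tested. Without wild-type replicate 2 the 43 genes called in dP2 cells became 28.

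In pro-B cells lacking Pax5, Ighv5-2 took 37.6% ± 1.55 (n = 3) against 6.79% in the 1 control library, and the distal share was 6.68% ± 0.0559 against 43.9%. Of 121 genes tested 41 were called, and 112 were called with 3 more controls of the same flow cell. With 1 control the spread was estimated from the mutant libraries alone, so the count says little and the values are given as measured. As deposited, Ighv5-2 was at 2.61% ± 1.19 against 2.40%. In the cells labelled as lacking Eed, Ighv5-2 rose from 6.64% ± 0.501 (n = 2) to 22.6% ± 3.79 (n = 4), and the distal share went from 47.0% ± 0.391 to 13.1% ± 4.07. Ighv1-80, Ighv1-59, Ighv1-83 and Ighv1-84 were listed at 0 in all 4 libraries. The exact permutation p for the distal share was 0.25 and 0.06667, each the smallest its design allows. The listed V total was low in both, at 6.99% ± 3.25 against 35.4% without Pax5, where the lowest library is labelled with 1 Rag2 allele, and 2.69% ± 0.589 against 38.0% ± 3.28 without Eed. As deposited, Ighv5-2 was at 0.612% against 2.52% in the Eed comparison, lower instead of higher. All 4 of these mutants carried Cre at Rag1, a recombinase gene, and neither control did, so the comparison does not separate Cre at Rag1 from loss of Eed. Only 18 of 120 genes were called in the Eed comparison, which became 34 without replicate 1 of the cells labelled as lacking Eed. Across genes, which are not independent replicates, the share changes in dP1,2 homozygous cells correlated with those without Pax5 (Spearman rho = 0.788 over 118 genes) and without Eed (0.777 over 117 genes).

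**Figure D2:**
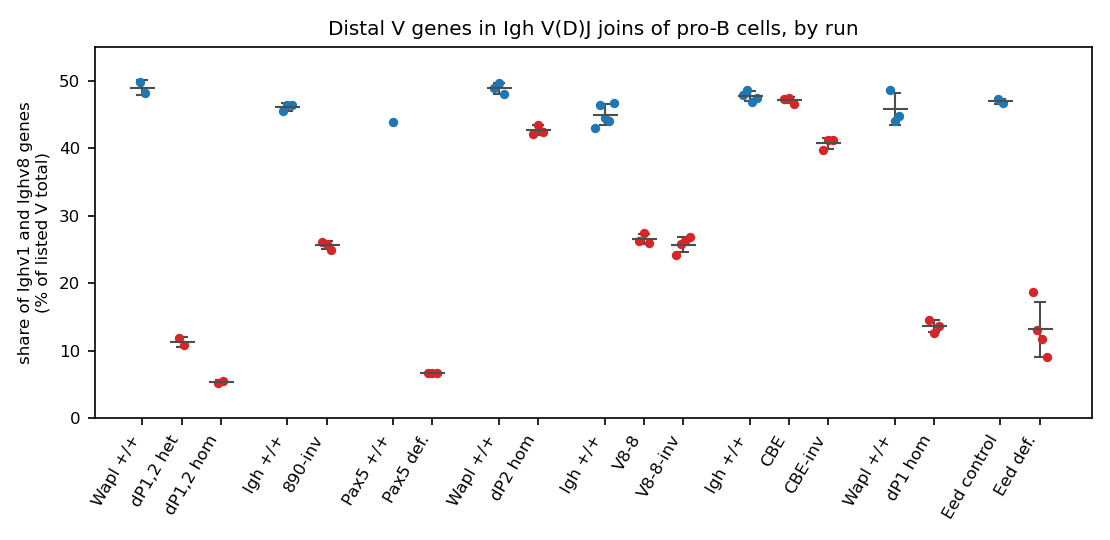
Share of the distal families (Ighv1 and Ighv8) in percent of the listed V total for each library (points), by sequencing run, with mean and SD; blue marks controls and red mutant groups. Control groups average 43.9 to 49.0%, dP1,2 homozygous cells at 5.40%, and CBE cells at 47.1%.

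**Figure D3:**
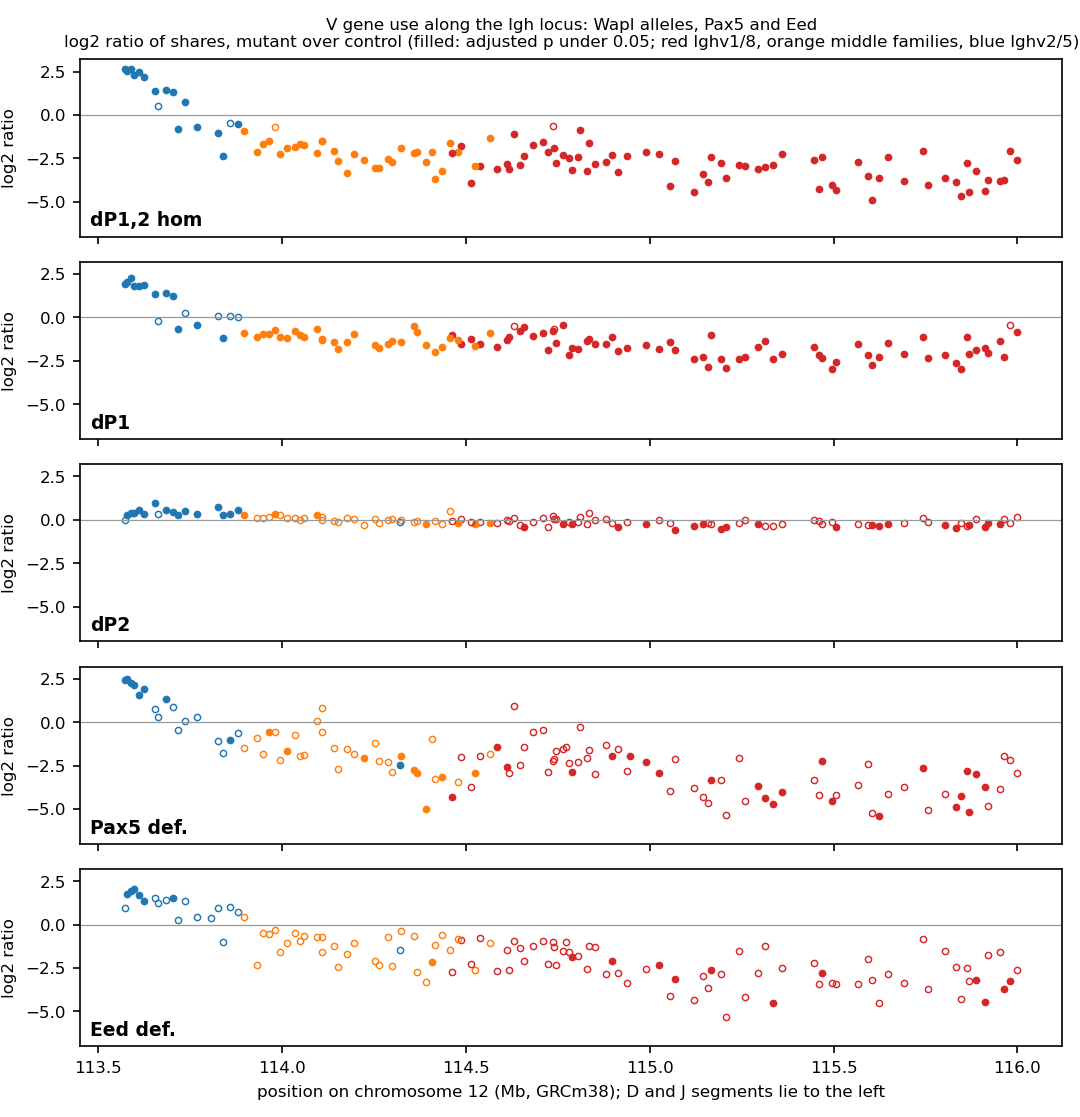
Log2 ratio of the share of each V gene (mutant over control, with 0.02 added to each share) against its position in Mb on chromosome 12; filled points passed limma's test, and colours mark distal (red), middle (orange) and proximal (blue) families. In the dP1,2 panel 10 proximal genes rose and 5 fell, and 68 distal genes fell. As deposited, 3 proximal genes were called higher and 11 lower.

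The 890-inv allele lost nearly all use of a block of distal genes. Ighv8-8, on chromosome 12 from 115294066 to 115294362, fell from 1.32% ± 0.0449 to 0.0146% ± 0.0115 (n = 3 each, adjusted p = 9.73e-16), and Ighv1-55 fell from 1.325% ± 0.137 to 0.00415% ± 0.00271. The 45 genes from Ighv1-49 (start 115055223) to Ighv1-79 (end 115888389), a block chosen after the values were seen, took 21.3% ± 0.525 of control joins and 0.689% ± 0.0351 of mutant joins, Ighv8-8 not counted. The 7 genes from Ighv1-80 outward went from 3.47% ± 0.144 to 2.03% ± 0.483. The middle families went from 28.5% ± 0.421 to 42.3% ± 0.333, with Ighv10-1 rising from 1.62% to 3.48%, and Ighv5-2 rose from 7.97% to 11.1%. As deposited the middle families were at 13.1% and 11.8%, and Ighv5-2 at 3.65% and 3.11%. In all, 90 of 120 genes were called, 37 higher and 53 lower, against 8 higher and 89 lower as deposited, and the exact permutation p for the distal share was 0.1, the smallest allowed. The p-values of single genes lean on spread that limma pooled across genes (20.6 degrees of freedom for 6 libraries).

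On the V8-8 and V8-8-inv alleles the same block of 45 genes took 0.549% ± 0.0292 (n = 3) and 0.431% ± 0.0463 (n = 4) of joins, against 20.4% ± 1.29 in controls (n = 5). The alleles differed at Ighv8-8, which took 1.27% ± 0.118 in controls, 0.551% ± 0.0934 on V8-8 and 0.0522% ± 0.0270 on V8-8-inv. It was the 1 gene of 122 called between the mutant alleles (log2 difference -3.07, adjusted p = 6.57e-06), and 7 had an unadjusted p under 0.05. Ighv1-72 went from 1.45% in controls to being listed at 0 on both. The distal share was 44.9% ± 1.56 in controls, 26.6% ± 0.792 on V8-8 (exact permutation p = 0.01786, adjusted 0.116) and 25.7% ± 1.13 on V8-8-inv (exact permutation p = 0.007937, adjusted 0.103). The middle families were higher at 42.5% ± 1.13 and 41.7% ± 2.43 against 29.6% ± 0.249, and 77 and 82 genes were called. As deposited the middle families were at 12.7% in controls, 14.1% on V8-8 and 10.9% on V8-8-inv, where 2 middle genes were called higher and 14 lower instead of 17 and 4 by share. The listed V total was 42.95% ± 3.32, 33.2% ± 3.09 and 26.0% ± 7.55, and V8-8-inv replicate 2 carries further genotype text in its label.

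On CBE, 4 of 121 genes were called: Ighv1-47 rose from 1.13% ± 0.0686 (n = 4) to 1.75% ± 0.0922 (n = 3), Ighv1-12 rose, and genes further outward, Ighv1-49 (1.11% to 0.687%) and Ighv1-50 (0.758% to 0.513%), fell. On CBE-inv, Ighv1-49 fell to 0.171% ± 0.0366, Ighv1-53 from 0.940% to 0.168%, Ighv1-55 from 1.43% to 0.309% and Ighv8-8 from 1.354% to 0.442%, while Ighv1-47 rose to 1.94% and Ighv10-1 from 1.66% to 2.42%. The block from Ighv1-49 to Ighv1-79 took 21.8% ± 0.505 in controls, 20.2% ± 0.648 on CBE and 12.1% ± 0.613 on CBE-inv. Within it, the fall on CBE-inv was smaller with distance from Ighv1-49 (Spearman rho = 0.891 across 33 genes, which are not independent replicates). The same correlation was 0.787 for CBE, against the same controls, and 0.844 between CBE-inv and CBE. The genes from Ighv1-80 outward were at 3.80% on CBE-inv and 3.68% in controls. Between CBE-inv and CBE, 57 of 121 genes were called, 26 higher and 31 lower, against 5 and 32 as deposited. The distal share was 47.7% ± 0.752 in controls, 47.1% ± 0.464 on CBE (exact permutation p = 0.2857) and 40.7% ± 0.846 on CBE-inv (exact permutation p = 0.02857, the smallest allowed, adjusted 0.124). In this run limma pooled the spread of all genes (847 degrees of freedom for 10 libraries), so small differences could pass.

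**Figure D4:**
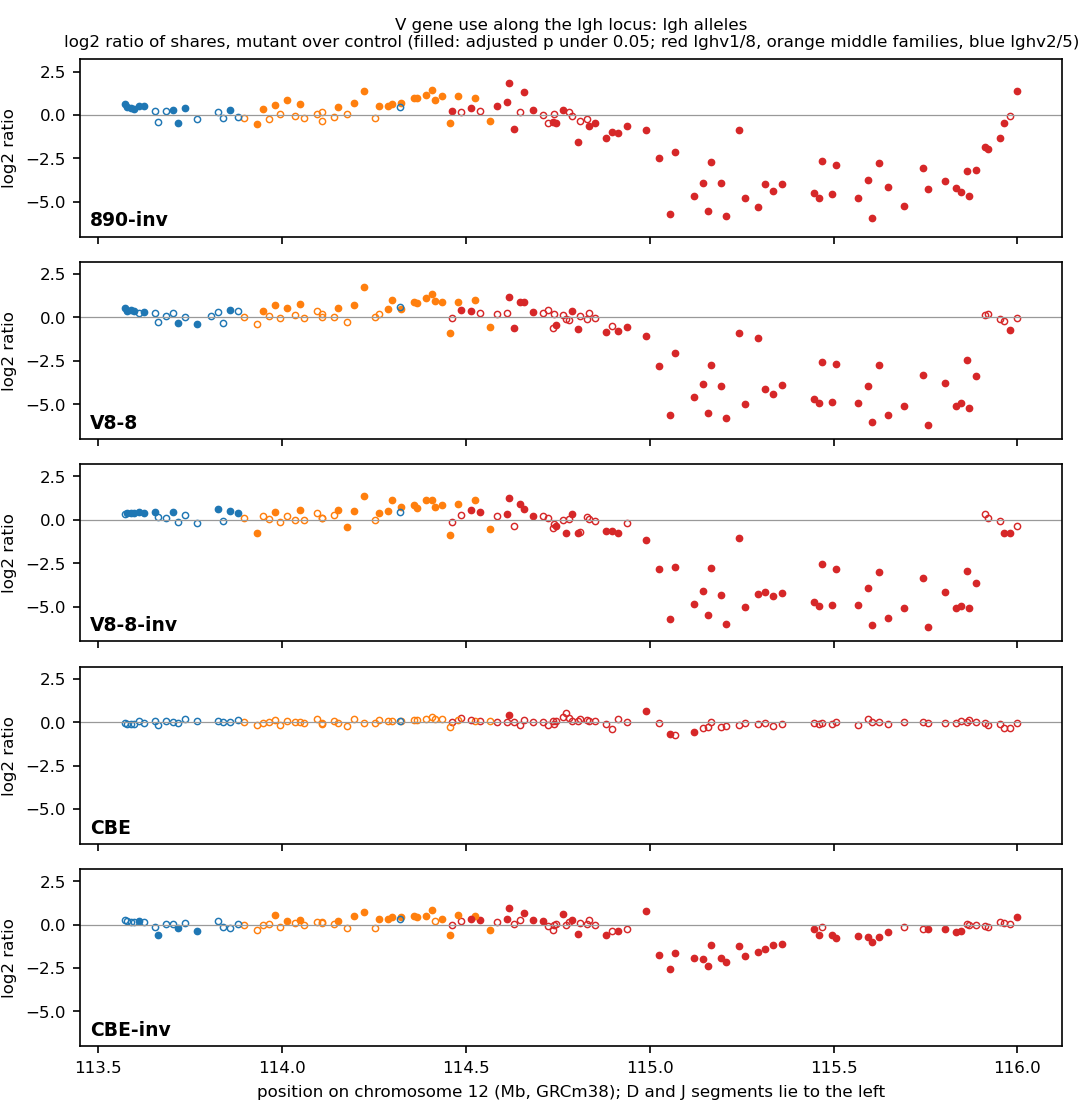
Log2 ratio of the share of each V gene (mutant over control, with 0.02 added to each share) against its position in Mb on chromosome 12 for the Igh alleles; filled points passed limma's test, with colours as in the plot of the Wapl alleles. The block from Ighv1-49 to Ighv1-79 falls to 0.689% of joins on 890-inv and 12.1% on CBE-inv.

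RNA of dP1,2 homozygous pro-B cells differed at 2153 of 12465 genes, 953 higher and 1200 lower. Pgf, a placental growth factor, rose from 2.27 ± 0.545 to 57.9 ± 12.5 TPM (n = 2 each, 17.9-fold, adjusted p = 0.000125), Igf1 from 1.97 to 28.2 TPM, and Enpep, the BP-1 surface antigen, from 20.3 to 237.2 TPM. Cldn4 fell 13.1-fold and Cxcr5, a chemokine receptor of follicular B cells, from 28.8 to 2.42 TPM. Of 15 genes activated by Pax5, 9 rose and 1 fell (10 and 2 adjusted over the list alone), among them Ikzf3 (30.5 to 76.9 TPM) and Irf4 (109.9 to 223.1 TPM), with adjusted p = 0.349 with an estimated correlation. Pre-B cell receptor signalling genes rose at 5 of 12, such as Cd79b (1620 to 3199 TPM) and Syk (adjusted p = 0.325 with an estimated correlation). Of 13 B-lineage transcription factors and Il7r, Il7r (115.3 to 230.5 TPM), Myb and Pax5 rose (adjusted p = 0.371 with an estimated correlation). Rag1, a subunit of the recombinase, rose from 399.7 ± 70.9 to 727.7 ± 144 TPM. Glycolysis genes fell at 11 of 19, among them Ldha (613 to 362.1 TPM) and Pfkl (adjusted p = 0.148 with an estimated correlation).

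In the same pro-B libraries, Polycomb targets gave 2 rises and 5 falls of 10, with Hoxa7 falling 5-fold and Cdkn2a, an inhibitor of the cell cycle, rising from 0.708 to 6.12 TPM (adjusted p = 0.349 with an estimated correlation). Polycomb repressive complex 2 subunits fell at 4 of 11, with Suz12 at 74.1 against 99.6 TPM (adjusted p = 0.349 with an estimated correlation). Of 10 p53 targets 4 rose, with Cdkn1a at 205.6 against 109.8 TPM (adjusted p = 0.297 with an estimated correlation). Distal V genes fell at 42 of 55 and middle ones at 20 of 27 (adjusted p = 0.148 with an estimated correlation for each), while proximal ones rose at 4 and fell at 9 of 18 (0.297, an adjusted p with an estimated correlation). Cohesin genes (1 up, 1 down of 15), cell cycle (0 of 18), interferon response (0 of 10), myeloid (1 up of 15), plasmacytoid dendritic (1 up of 5), erythroid (2 up of 4), plasma cell (1 down of 5), T and innate lymphoid (1 down of 9) and immediate early lists (1 up of 10) were not called by fry. Transcripts from chromosome Y were absent in the mutant libraries (Eif2s3y 11.4 TPM in controls and listed at 0), the sex-linked list fell at 3 of 5 (adjusted p = 0.371 with an estimated correlation), and without genes of chromosomes X and Y, a choice made after seeing this, 2105 genes were called. Leaving out wild-type replicate 1, wild-type replicate 2 or mutant replicate 2 gave 898, 929 and 889.

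In dP1,2 pre-B cells, 376 of 12465 genes were called, 217 higher and 159 lower. The chromosome Y transcript Eif2s3y was at 10.8 and 28.9 TPM in the wild-type libraries and at 0.067 and 0 TPM in the mutant ones. Sex therefore went with genotype in this comparison, and the 2 cannot be told apart within it. In cultured cells the wild-type libraries lacked chromosome Y transcripts, as did mutant replicate 3. Wapl was at 7.41 to 12.2 TPM in the wild-type and 30.85 to 52.8 TPM in the mutant libraries there. For Wapl these values argue against sex as the cause, and other genes were not weighed in this way. The surrogate light chain genes Vpreb1 (21.8 ± 2.45 to 216.7 ± 40.1 TPM, n = 2 each, 9.48-fold, adjusted p = 1.99e-05), Igll1 (38.8 to 239.2 TPM) and Vpreb2 rose, as did Dntt, the enzyme that adds nucleotides at joins (5.05 to 21.7 TPM). With these, the pre-B cell receptor list rose at 3 of 12 (adjusted p = 0.248 with an estimated correlation). Wild-type pro-B cells held far more of these transcripts, with Vpreb1 at 2349 and 2307 TPM and Dntt at 2218 and 2268 TPM. Mutant pro-B cells had Vpreb1 at 2765 and 3127 TPM and Dntt at 1733 and 1707 TPM. Pro-B cells mixed in would thus raise the 2 genes by amounts far closer than those seen, which argues against pro-B cells alone. A few other earlier cells among the sorted mutant pre-B cells could give such rises, and this was not tested. The IGHG2b row rose from 2.23 to 102.1 TPM. Mmp14, a membrane metalloproteinase, fell from 22.8 to 1.89 TPM, and H2-Aa and H2-Ab1, genes of antigen presentation, fell. Among V gene transcripts, Ighv2-2 rose from 89.2 ± 0.460 to 1085 ± 13.5 TPM, Ighv1-55 fell from 130.5 to 4.13 TPM and Ighv8-8 from 207.2 to 14.6 TPM. Distal V genes fell at 46 of 55 (adjusted p = 0.0375 with an estimated correlation), middle ones at 21 of 27 (0.0674, an adjusted p with an estimated correlation), and proximal ones rose at 8 and fell at 3 of 18 (0.0971, likewise). Leaving out wild-type replicate 1, wild-type replicate 2 or mutant replicate 2 gave 215, 186 and 195 called genes, and a fit of the 2 groups alone gave 246.

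The mutant effect differed between the stages at 418 genes, 245 with a higher log2 effect in pre-B cells and 173 with a lower one. Chromosome Y transcripts were absent or nearly so in the mutants of both stages, so sex went with genotype in both effects. Vpreb1 (log2 difference 2.91, adjusted p = 0.00108), Dntt (2.29, adjusted p = 0.000713) and Igll1 (2.16) had the higher effect in pre-B cells, and Ikzf3 (-1.11), Irf4 (-1.09) and Il7r (-0.90) the lower. For Vpreb1, Dntt and Igll1 the limit about earlier cells among the sorted pre-B cells holds here too. Proximal V genes had a higher effect at 9 of 18 (16 adjusted over the list alone), which fry and camera both called (adjusted p = 0.0192 with an estimated correlation). For the Polycomb target, glycolysis and distal V gene lists, fry gave adjusted p = 0.0519 in the order of groups used and 0.0446 in the other order. Counts without 1 library at a time were 131 and 140 without pro-B wild-type replicates 1 and 2, 209 and 166 without pro-B mutant replicates 1 and 2, 185 and 151 without pre-B wild-type replicates 1 and 2, and 185 without pre-B mutant replicate 2.

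In cultured dP1,2 pro-B cells, 2703 of 12457 genes were called, 394 higher and 2309 lower, and after quantile normalization 1477 and 1600. The median gene lay at -0.18 on the log2 scale, which quantile normalization moved to 0.04. All 10 interferon response genes measured fell, among them Isg15 (242.5 ± 49.0 to 21.3 ± 4.98 TPM, n = 2 and 3, adjusted p = 0.000127), Oasl2 (26.4 to 1.45 TPM) and Ifit1, and all 10 did so after quantile normalization (adjusted p = 0.164 with an estimated correlation). All 6 light chain genes fell, with Igkc at 49.9 against 182.4 TPM (adjusted p = 0.164 with an estimated correlation). Dntt fell from 240.2 to 75.1 TPM, opposite in direction to pre-B cells, though the difference between these experiments was not tested. In sorted pro-B cells Dntt was also lower, at 1733 and 1707 TPM in the mutant against 2218 and 2268 TPM in wild type. Il7r (29.4 to 78.0 TPM), Ikzf3 and Irf4 rose. Distal V genes fell at 32 of 34, middle ones at 17 of 17 and proximal ones at 9 of 14 (adjusted p = 0.14, 0.0982 and 0.585 with an estimated correlation). Xist fell from 49.95 to 7.75 TPM, and without genes of chromosomes X and Y 2691 genes were called. Without wild-type replicate 1 or 2 the count was 505 and 865, without mutant replicate 1 or 2 it was 5954 and 1478.

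Progenitors lacking Pax5 differed from wild-type pro-B cells at 4441 of 12023 genes, 1869 higher and 2572 lower, and after quantile normalization 2427 and 2400. The median gene lay at -0.11 on the log2 scale and at -0.02 after quantile normalization. Pax5 itself was 8.89-fold lower, at 41.1 ± 2.71 (n = 2) against 373.3 ± 26.8 TPM (n = 3, adjusted p = 2.93e-06). Jchain, the joining chain of secreted antibodies, rose from 0.495 to 620.2 TPM and Stum from 0.475 to 158.5 TPM. All 14 genes activated by Pax5 fell, among them Cd72 (181.5 to 1.69 TPM) and Nedd9 (175.6 to 12.4 TPM, adjusted p = 0.114 with an estimated correlation), and 6 of 7 repressed genes rose, with Flt3, a cytokine receptor of progenitors, rising 22.7-fold to 357.3 TPM (adjusted p = 0.404 with an estimated correlation). Those lists were written from genes already known to depend on Pax5. Lef1, a transcription factor of early B cells, fell from 535.4 to 6.13 TPM. Pre-B cell receptor genes fell at 10 of 12 (adjusted p = 0.198 with an estimated correlation), and cohesin genes fell at 10 and rose at 1 of 15, the rise being Wapl and the falls including Rad21 (361.7 to 201.2 TPM, adjusted p = 0.685 with an estimated correlation). Cell cycle genes fell at 11 of 18 (adjusted p = 0.685 with an estimated correlation). Distal V genes fell at 23 and rose at 6 of 49, which fry did not call (adjusted p = 0.718 with an estimated correlation). Leaving out mutant replicate 1 or 2 gave 1947 and 1652 called genes.

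RNA of cells labelled as lacking Eed differed at 2691 of 12338 genes, 1559 higher and 1132 lower. Of 26 Polycomb targets 25 rose, and Cdkn2a went from 0.661 ± 0.324 (n = 4) to 261.5 ± 50.5 TPM (n = 5, 153-fold, adjusted p = 4.71e-08). Hoxc4, Hoxb8 and Hoxb7, regulators of body axis identity, rose from at most 0.0736 TPM to between 8.79 and 13.7 TPM. The list had adjusted p = 0.0684 with an estimated correlation. Esx1 and Crabp1 rose from 0.0893 and 0.133 to 74.5 and 75.9 TPM. Of 11 p53 targets 9 rose, with Phlda3 at 141.1 against 15.3 TPM (adjusted p = 0.0684 with an estimated correlation), and Cd74 of antigen presentation rose from 38.1 to 484.6 TPM, with mature B cell markers rising at 5 of 9 (adjusted p = 0.211 with an estimated correlation). Dntt fell from 1893 ± 771 to 650.4 ± 143 TPM, and V(D)J recombination genes fell at 4 of 12 (adjusted p = 0.352 with an estimated correlation). Eed RNA was 1.56-fold higher in the cells labelled as lacking it (adjusted p = 0.0443), which does not report on the protein. The counts without control replicates 1 to 4 were 1413, 5064, 4677 and 1181, and without mutant replicates 1 and 2 they were 1420 and 1314.

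In immature B cells labelled as carrying 1 copy of 890-inv and 1 wild-type Igh allele, 62 of 11406 genes were called, 26 higher and 36 lower. Ighv8-8 fell from 334.8 ± 23.6 to 4.11 TPM (n = 2 each, 66.8-fold, adjusted p = 2.74e-05) and Ighv1-55 from 204.4 to 3.05 TPM, below what the wild-type allele on the label would leave if both alleles were expressed alike, while Ighv6-3 rose from 152.5 to 442.8 TPM and Ighv2-2 from 168.5 to 334.2 TPM. Distal V genes fell at 27 and rose at 5 of 58 (adjusted p = 0.154 with an estimated correlation), and middle ones rose at 10 of 27, which fry did not call. Without mutant replicate 1 or 2 the count was 32 and 38. Wapl was at 283.8 ± 171 TPM in these controls and 34.0 ± 9.58 TPM in the mutant (adjusted p = 0.0517), not called. The controls themselves were at 162.6 and 405 TPM. Controls of the CBE and V8-8 immature B cell runs were at 29.1 ± 3.45 and 17.6 ± 3.65 TPM. It was thus the 890-inv controls that stood apart from the other runs, and the cause was not tested. The CBE and CBE-inv cells were also labelled with 1 wild-type Igh allele. With CBE, Snord95 was the only gene called (294 genes had an unadjusted p under 0.05), and none was called without any 1 of the 5 libraries. The chromosome Y transcript Eif2s3y was at 26.9, 17.6 and 5.84 TPM in the controls and listed at 0 in both CBE libraries. Sex thus went with genotype there. In the CBE-inv libraries Eif2s3y was at 36.6 and 0 TPM. With CBE-inv 10 of 11987 genes were called, among them Ighv8-8 (254.1 ± 16.2 to 63.2 ± 3.34 TPM, adjusted p = 0.000218), Ighv1-55 (119 to 28.5 TPM) and Ighv1-50, again below what that allele would leave, and 6 were called without CBE-inv replicate 1. Between CBE-inv and CBE 5 genes were called, all V genes lower with CBE-inv, and 14 and 8 without CBE-inv replicate 1 or 2.

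In immature B cells with V8-8 or V8-8-inv over a deleted allele, 28 and 26 of 11895 genes were called (n = 2 each). Eif2s3y was at 13.3 and 32.7 TPM in controls, 0 and 17.0 TPM with V8-8, and 23.9 and 10.5 TPM with V8-8-inv. Sex was thus not matched between these libraries. Ighv8-8 fell from 174.9 ± 11.9 to 64.6 ± 2.70 TPM with V8-8 (adjusted p = 0.00237) and to 6.13 ± 0.0455 TPM with V8-8-inv (adjusted p = 2.51e-05), and it differed 9.2-fold between them (adjusted p = 0.000272). Ighv8-12 and Ighv1-53 were at 90.1 and 68.4 TPM in controls and listed at 0 with both alleles. Distal V genes fell at 21 and rose at 2 of 54 with V8-8 (adjusted p = 0.069 with an estimated correlation) and fell at 22 and rose at 1 with V8-8-inv (adjusted p = 0.255 with an estimated correlation). Middle V genes rose at 1 of 27 with V8-8 (15 adjusted over the list alone), a list that fry and camera both called (adjusted p = 0.0354 with an estimated correlation). With V8-8-inv none passed of 27 (12 higher and 2 lower adjusted over the list alone), and camera did not call the list (adjusted p = 0.0527 with an estimated correlation). The median gene lay at -0.11 with V8-8-inv and 0.01 after quantile normalization, and between the alleles at -0.15 and 0.01. Without control replicate 1 the V8-8 count was 422, without control replicate 2 the V8-8-inv count was 1753, and the 5 genes called between the alleles became 2, 2, 1 and 1 without each of the 4 mutant libraries.

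CTCF peaks were largely shared between wild-type and 890-inv cultured pro-B cells. The wild-type libraries had 36687 and 36133 peaks and the 890-inv libraries 34754 and 29352. Of wild-type peaks 85.6% ± 6.87 were overlapped by an 890-inv peak over the 4 pairs of libraries, against 94.1% ± 0.919 between the wild-type libraries and 90.8% ± 11.1 between the 890-inv libraries. Of 890-inv peaks 97.6% ± 1.91 were overlapped by a wild-type peak. On build mm9, the interval on chromosome 12 from 116431886 to 117046791 (Ighv1-54 to Ighv8-14) held 22 peaks in each wild-type library and 19 and 14 in the 890-inv libraries. The overlaps and this interval take the 890-inv peaks as lying on mm9 itself, while the series text names a modified build for them. With 2 libraries each and no peak heights, no test was made.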

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

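The tests of explanations below were all chosen only after the results were seen; the splits of the samples were planned.

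The effect of the dP1,2 genotype differed between pre-B and pro-B cells at 418 genes by the test of the difference itself. Sex went with genotype in both stages. Among 24 groups tested, 4 held a library far from the others, and chance flags about 1 in 20 groups. V8-8-inv replicate 2 had a listed V total of 37.35%, the highest of 4, and its genotype label carries further text naming the CBE alleles. Wild-type replicate 3 of the CBE run had 42.72%, the lowest of 4. Eed control replicate 2 had 508.8 TPM of Pax5, the highest of 4, and replicate 1 of the cells labelled as lacking Eed had 222.5 TPM of Eed, the highest of 5.

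Eed control replicate 2 was apart in more than Pax5: its cell cycle genes had a median of 105 TPM, against 251 to 500 TPM in the other 8 libraries, and leaving it out raised the called genes from 2691 to 5064. Many cells of another type in that library stay open: its genes activated by Pax5 stood at 1.65 times the median of the other controls, which goes against that, but its myeloid markers had a median of 28.4 TPM against 4.41 to 13.5 TPM in the other 8 libraries, which goes towards it. A library series effect would show in its partners, and its cell cycle median was 0.24 of the lowest of theirs. A knockout library under a control label would hold much Cdkn2a, which was at 0.42 TPM there and at 211 to 341 TPM in the libraries labelled as lacking Eed. A control with fewer dividing cells stays open as a hypothesis and was not tested.

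Other splits of the same libraries were run where each group held at least 3. For the Eed RNA comparison 2 of 99 splits gave as many genes, the real one with 2691 and another with 2805. A count of that size was therefore not reached by the genotype labels alone, though 2 of 99 is a share under 1 in 20. For V8-8 1 of 56 splits gave 77 genes (highest other 1) and for V8-8-inv 1 of 100 gave 82 (highest other 64). For CBE-inv 1 of 35 gave 65 (highest other 28). Each share is under 1 in 20 but is not adjusted for the number of comparisons. The exact permutation tests of the distal share had adjusted p = 0.116, 0.103 and 0.124 for these alleles. Chance is therefore not excluded over all the comparisons made. For CBE 2 of 35 splits gave the 4 genes or more (highest other 5) and between V8-8-inv and V8-8 4 of 35 gave 1 or more (highest other 2), so chance is not excluded for those counts. For 890-inv (90, highest other 0), dP2 (43, highest other 0), dP1 (108, highest other 0) and CBE-inv against CBE (57, highest other 0), 1 of 10 splits was the real one and 10 splits are too few for a share under 0.05.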

How the results depend on the processing

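The alternative that leaves out genes of chromosomes X and Y, the differences in listed V total and the other order of groups for fry were chosen after the data were seen; the rest were planned. Of the main results, 93 kept their side of the threshold or stayed within 1.5 times under the other settings and 14 did not. Of the named genes, 2951 values stayed, 152 lost their call, 15 gained one and 19 turned direction; leaving out libraries, 4441 stayed, 596 lost their call, 39 gained one and 0 turned. Depth is unknown, so the limit it sets cannot be given. The edgeR alternative and the choice of stronger CTCF peaks were not run, since the files hold no counts and all scores are 0. No paired analysis was possible because the labels give no replicate numbers that pair libraries.

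Settings that moved a count were these, and the cause was not tested except where stated: dP1,2 pre-B cells fitted as 2 groups alone, 246; CBE RNA with no filter 9 and quantile normalization 0; CBE-inv against CBE RNA with no filter 13; V8-8-inv against V8-8 RNA with pseudocount 0.1 TPM 3, no filter 11 and quantile normalization 3; Pax5 V(D)J with pseudocount 0.1 71, as deposited 90, and with 3 more control libraries of the same flow cell 112, where more libraries were compared; CBE-inv against CBE V(D)J as deposited 37; Eed V(D)J with no filter 29 and as deposited 119, where the fall of the whole total enters every gene. Over all comparisons fry called 55 lists, camera with an estimated correlation 3, and fry with the groups in the other order 58, the added ones being 3 lists of the difference between pre-B and pro-B effects. Without genes of chromosomes X and Y the dP1,2 counts were 2105, 364, 410 and 2691 for pro-B, pre-B, their difference and cultured cells. Leaving those genes out does not remove effects of sex on other genes.

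Log2 changes that turned with values as deposited, whose falling total is the cause by construction, were -0.0309 for Ighv5-6 in dP1,2 cells; -0.34 for Ighv2-2 and -0.24 for Ighv5-2 in 890-inv; -0.517 for Ighv5-6, -0.882 for Ighv2-3, -0.327 for Ighv5-4, -0.236 for Ighv2-2 and -0.00169 for Ighv5-2 without Pax5; -0.0256 for Ighv1-26 and -0.00607 for Ighv5-2 in V8-8; -0.429 for Ighv1-26, -0.359 for Ighv2-2 and -0.381 for Ighv5-2 in V8-8-inv; -2.29 for Ighv5-12, -2.13 for Ighv2-3, -1.8 for Ighv5-4, -1.92 for Ighv2-2 and -2.09 for Ighv5-2 without Eed. With pseudocount 0.1 TPM the difference of stages for Ighv1-80 became 0.0911, and the cause was not tested.

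Leaving out 1 library, which leaves some groups with 1 and assumes it varies like the others, gave these lowest and highest counts: pro-B 889 to 1634, pre-B 186 to 472, their difference 131 to 361, cultured 505 to 5954, Pax5 1652 to 5049, Eed 1181 to 5064, 890-inv 32 to 56, CBE 0 to 0, CBE-inv 6 to 13, CBE-inv against CBE 4 to 14, V8-8 22 to 422, V8-8-inv 21 to 1753 and V8-8-inv against V8-8 1 to 2 for RNA; dP2 28 to 38 and Eed 14 to 34 for V(D)J. The difference in listed V total between CBE and control ranged from -1.905 to 1.371, around -0.2646. CTCF overlap ranged from 79.68% to 91.54%.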

Other observations

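The tests of explanations in this part were all chosen only after the results were seen.

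Other groups moved as well, by limma and fry. In progenitors lacking Pax5, T and innate lymphoid markers rose at 4 and fell at 1 of 6, with Lck at 197.1 against 65.9 TPM (adjusted p = 0.685 with an estimated correlation), and B-lineage transcription factors fell at 7 and rose at 2 of 13, with Tcf3 at 374.7 against 1261 TPM (adjusted p = 0.685 with an estimated correlation). In cells labelled as lacking Eed, the same T and innate lymphoid list rose at 4 and fell at 1 of 6, with Thy1 at 130.1 against 31.6 TPM (adjusted p = 0.312 with an estimated correlation). Distal V gene RNA there fell at 22 of 33 and proximal V gene RNA at 11 of 13 (adjusted p = 0.139 and 0.236 with an estimated correlation). In cultured dP1,2 pro-B cells, Polycomb targets fell at 8 of 17, with Sox9 at 11.6 against 22.9 TPM (adjusted p = 0.585 with an estimated correlation).

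The CTCF peaks of the 890-inv libraries were compared with mirrored wild-type peaks in the interval from Ighv1-54 to Ighv8-14. Unmirrored, 13 to 19 peaks overlapped, and the best mirrored placement gave 4 to 5. Mirroring 1 wild-type library onto the other gave 5 as well, and 1 890-inv library onto the other gave 4, so mirrored matches did not exceed that level. In this interval the deposited 890-inv peaks thus matched mm9 positions unmirrored. The series text, however, places the 890-inv peaks on a build modified for the allele.

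The proximal families took a larger share in the Wapl mutants. Fewer distal and middle joins raise the share of the rest without any gain. The value examined was the proximal part of the deposited total once distal and middle joins are taken out of it. Fewer such joins alone would leave that part unchanged if the lost joins leave the total. If they become unlisted reads, that part would fall. It changed by -8.11 percentage points in dP1,2 homozygous cells and by -3.89 in dP1 cells, where unlisted reads made up more of the total. The explanation allows such a fall, and a gain of proximal joins could also be hidden, so it stays open in both. In dP2 cells that part rose by 10.36, from 17.05% ± 2.39 to 27.4% ± 1.52 (n = 3 each), which the explanation alone does not allow. A gain of proximal joins in dP2 cells stays a hypothesis. The listed V total rose by 8.665 percentage points there, so unlisted reads made up less, which would raise that part too. No biological explanation was tested.

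In cultured dP1,2 pro-B cells most calls were falls, and the TPM scaling may account for that: after quantile normalization 52% of calls were falls, against 85.4%. It cannot account for the interferon response genes, of which 10 of 10 stayed lower after quantile normalization. The sex of the mice stays open: mutant replicate 3 lacked transcripts of chromosome Y as the wild type did, and the median interferon gene there lay at -3.41 on the log2 scale, while the wild-type libraries differed by 0.388, but 1 library does not settle it for the other 2. Whether the genotype or the culture of the 2 groups differs here was not tested, since no label gives culture dates.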
